A study of Mus musculus with 14 samples.

How the data were processed

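Total RNA of mouse lung was sequenced in 14 libraries: 4 of Men1 knockout and 4 of their wild-type mice, and 3 of Kmt2a knockout and 3 of their wild-type mice. The labels give lung as tissue and source, while the extraction protocol names macrophages of the peritoneal cavity. Lung is used here. In the authors' deposited table, the Kmt2a wild-type means are 1958770 for Scgb1a1, 26526 for Sftpa1 and 23566 for Ager, epithelial genes of the lung that macrophages do not carry at such levels. For the Men1 libraries, whose table holds no alveolar type 1 or type 2 list member, the conflict was left open. Libraries were made with the NEBNext Ultra kit, which keeps no strand information. The submitters' processing notes list HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1, with the builds GRCm38 and mm10, without giving roles.

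The Men1 table holds raw counts per library, as deposited, and normalized counts, a signal the authors made by dividing each count by 1 size factor per library. The size factors range from 0.811 (KO-6086) to 1.38 (KO-6076). It also holds the deposited log2 fold change, and the p and adjusted p value columns as deposited. The table is limited to genes with p below 0.05 and an absolute log2 fold change of at least 1, and gives no adjusted p for 557 of its 772 genes. The Kmt2a table, in which the knockout is called MLL, holds a deposited signal, the mean of normalized counts per group without values per library, besides the deposited log2 fold change, p and adjusted p value. It is limited to an adjusted p below 0.05. Its wild-type column does not list its libraries and was taken as the wild-type group of the Kmt2a labels, which the deposited table does not state. The reads recovered from that column come from 3 libraries, as in that group. In the 70 genes of both tables, they correlated at 0.884 to 0.914 with each other and at 0.565 to 0.662 with the Men1 wild-type libraries (log2 reads with 1 added), with equal reads in at most 8 of the 70 genes, so they are not the Men1 wild-type libraries; which animals they are is not settled by this. In the Men1 table, 2 further wild-type columns of raw counts match no sample and were not used. Of the gene IDs, 260 of 772 in the Men1 table and 5 of 3956 in the Kmt2a table are absent from the GENCODE release for GRCm38 at hand, so the tables rest on different annotations.

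As both tables hold selected genes only, no new genome-wide test was made, which is the case the plan had set out for such tables. The authors' adjusted p, at a threshold of 0.05, and the sign of their log2 fold change are the call for each gene. Means, SDs and log2 ratios of group means were computed from the normalized counts (Men1, n = 4) or from the deposited means (Kmt2a). A log2 ratio is positive where the knockout is higher. In genes with both Kmt2a means of at least 10, it differed from the deposited log2 fold change by at most 0.024. A gene counts as not overlapping where every library of one group lies above every library of the other, which chance gives in 2.86% of genes with 4 against 4 libraries and in 10% with 3 against 3. Exact permutation p values for Men1 genes are over all regroupings of the 8 libraries on log2 values with a pseudocount of 1.

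The deposited Kmt2a means carry 15 significant digits, which allows the whole reads of the libraries behind them to be recovered. A mean is a sum of 3 whole numbers of reads, each multiplied by what 1 read of its library adds. Those steps were read from the lowest values of the table. Means up to 10000 resolved to 1 solution in 3841 of 3853 cases in the knockout and in all 3878 in the wild type, and 3813 genes had both means resolved. On 400 simulated means, all were resolved to the true reads, and none of 400 values without whole reads was resolved. The recovered libraries are called a, b and c. They serve for overlap, ranges, depth, left-out libraries, edgeR and its simulation, and the tests of the closing section.

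Gene lists for cell types, pathways, regulators and technical signs, 49 in all, were fixed before the data were seen. Each list with at least 3 members in a table was tested for direction, higher against lower, against all other genes of that table with Fisher's exact test. Members without a row, the greater part of some lists, are not counted, and all genes of a list means all that are in the table. The p values were adjusted by Benjamini-Hochberg over the lists of a comparison, 3 for Men1 and 41 for Kmt2a. On 200 tables with shuffled directions, none of 8200 list tests was called, and a list of 18 genes all set higher was always recovered. Shuffling gene by gene does not keep genes of a list moving together, so it cannot show how often such lists are called falsely. The list test takes each member as independent, and its p values can be too small where members rise or fall together. Genes of both tables were matched by ID, and their directions were compared with Fisher's exact test.

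Named genes follow a rule fixed beforehand. It takes genes past the threshold with a symbol other than a provisional one, a mean of at least 50 in the higher group and no overlap, up to 10 with the largest increase and 10 with the largest decrease. It adds up to 4 genes of each described list that passed (or up to 2 of the most abundant if none did) and the genes past the threshold in both tables. Parents of processed pseudogenes are the protein-coding genes that share the most 31-base sequences with them in the GENCODE transcripts, at least 10% of the pseudogene's.

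Depth can be judged only over selected genes: 11910 to 49541 raw reads per Men1 library over the 772 genes, with a median mean level of 5.63 normalized counts per gene, and 2986231 to 4496396 recovered reads per Kmt2a library over the resolved genes, with a median mean level of 432. In simulated data, a 4-fold change was called by edgeR in 10.5% of 200 changed Men1 genes and in 92.0% of 200 Kmt2a genes. Of unchanged genes, 0% and 0.72% were called. The cut was the authors' largest p among their calls, 0.000158 for Men1 and 0.00917 for Kmt2a. With cuts so unlike, the rates do not compare depth alone.

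Alternatives set out beforehand were a stricter adjusted p of 0.01, an absolute log2 fold change of at least 1, a mean of at least 10 or 50, medians in place of means, non-overlap in place of the adjusted p, pseudocounts of 1 and 10, other backgrounds of the list test and leaving out each library. Added after the data were seen were edgeR 4.0.16 quasi-likelihood tests on the selected genes, the left-out recovered libraries, a limit of the shared genes to protein-coding ones and backgrounds of the list test matched by gene length. Other normalizations and DESeq2 were not run, since selected genes give no basis for either, and other splits of the libraries were not counted, since the genes had been chosen on the real one. The groups share no replicate numbers, so no pairing was used. Work was done in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9) and R 4.3.3.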

Results

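Gene expression in mouse lung was compared between Men1 knockout and wild-type mice (4 libraries each) and between Kmt2a knockout and wild-type mice (3 libraries each). Men1 encodes menin, and Kmt2a encodes the histone methyltransferase MLL, which menin binds. Both deposited tables hold only genes the authors had selected, so the authors' adjusted p is the call for single genes. Neither Men1 nor Kmt2a has a row in the tables used here, so the genotype labels could not be checked on the knocked-out genes. Both tables are filtered, so if these genes were tested, neither passed the filter in its own knockout, and the data used here give no sign of the loss of either.

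In Men1 knockout lung, few genes passed the test, and most of those were higher. Of 772 genes in the table, 13 had an adjusted p below 0.05 in the authors' deposited table, 10 higher and 3 lower. The secreted zinc-alpha-2-glycoprotein gene Azgp1 stood at 400 ± 95.3 normalized counts (mean ± SD, n = 4) in the knockout and 186 ± 64.2 (n = 4) in the wild type. Follistatin (Fst), an inhibitor of activin, stood at 76.9 ± 9.02 against 34.2 ± 13.9, the heme-binding protein gene Hebp2 at 111 ± 5.50 against 50.5 ± 22.1, and apolipoprotein B (Apob) at 117 ± 20.3 against 43.3 ± 26.4. Hspa1a, an inducible heat shock protein gene, fell from 494 ± 281 to 75.9 ± 56.7, a log2 ratio of −2.70.

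The largest fall in the Men1 knockout was that of Gm6314, from 175 ± 72.6 to 1.33 ± 0.76 normalized counts (n = 4 each), with 1 to 3 raw reads in each knockout library. The third gene that fell was Gm56882, from 108 ± 87.4 to 29.9 ± 11.6. Its libraries overlapped: the wild type ran from 43.3 to 229 (WT-6097) and the knockout from 16.1 to 44.5. Among those that rose were corticotropin-releasing hormone (Crh, log2 ratio 2.26), the retinol-binding protein gene Rbp2 (2.44), Ldhb-ps (1.48), Gm14317 (1.13) and Hmgb1-ps8 (2.55). Gm6314, Gm56882, Crh, Ldhb-ps and Gm14317 lie outside the rule for named genes and were chosen after their values were seen. Without WT-6097, the log2 ratio of Hmgb1-ps8 was 3.48. Without KO-6075, that of Hspa1a was −3.37. Dmbt1, a scavenger receptor gene of mucosal surfaces, also passed, yet 1 library carried its mean: 240 normalized counts in KO-6086 against 4.72 to 11.3 in the other knockout libraries. Its log2 ratio was 5.37 with all libraries and 2.29 without KO-6086. With a pseudocount of 10, the log2 ratio was 2.71 for Dmbt1, 1.54 for Hmgb1-ps8 and 1.48 for Rbp2. Apob was also highest in KO-6086, at 145 normalized counts, against 99.1 to 116 in the other knockout libraries.

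In the authors' deposited table, the adjusted p was 0.0108 for Azgp1, 0.0147 for Hebp2, 0.0202 for both Fst and Hspa1a, 0.0414 for Apob and 0.0472 for Dmbt1. For 11 of the 13 genes no knockout library overlapped a wild-type library, which gives the smallest exact permutation p possible with 4 against 4 libraries (0.0286). Over the whole table, libraries did not overlap in 274 of 772 genes (35.5%, against 2.86% by chance). Those genes had been selected on the same libraries. An edgeR test on the reads of the 772 genes, chosen after the data were seen and cut at the authors' largest p among their calls (0.000158), called 2 of the 13, Gm6314 and Dmbt1. Its p for the others ran from 0.00037 for Hspa1a, 0.00056 for Rbp2, 0.00066 for Crh and 0.00087 for Hmgb1-ps8 to 0.042 for Fst, 0.050 for Hebp2 and 0.072 for Azgp1, with 0.021 for Apob. In simulated data it called 10.5% of 200 4-fold changes, and 28.6% of the 7 in genes with a mean of at least 50.

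**Figure D1:**
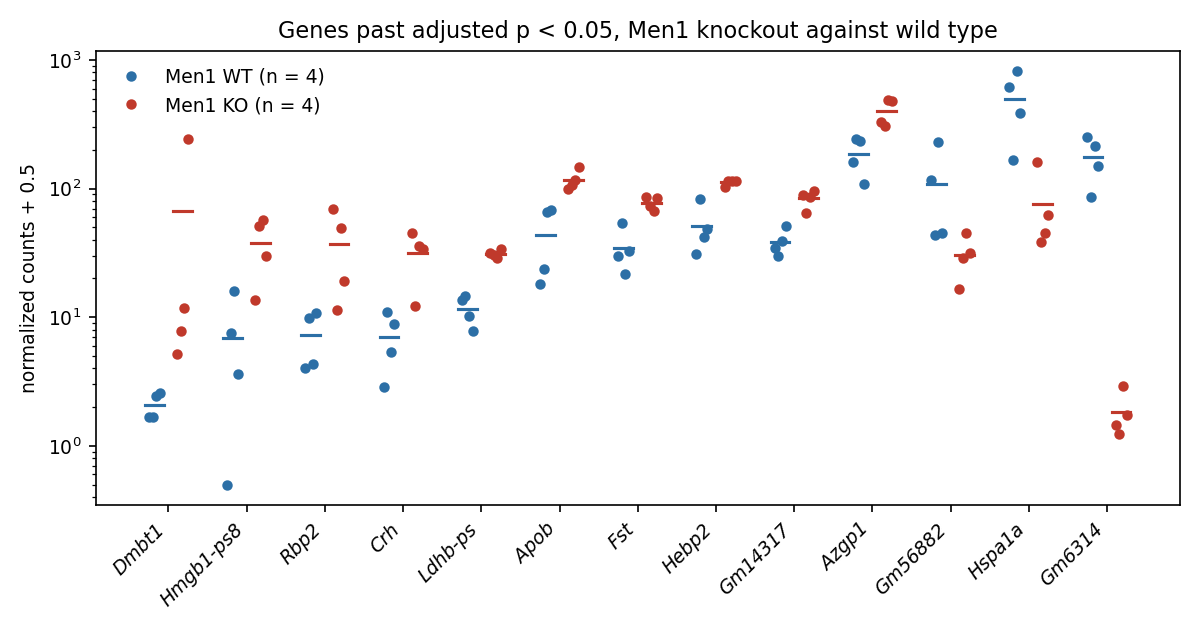
Normalized counts per library (dots, with 0.5 added for the log axis) and group means (bars) of the genes with an adjusted p below 0.05 in the authors' deposited table, Men1 knockout against wild type, ordered by log2 ratio.

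The neutrophil and erythroid markers in the Men1 table were all lower in the knockout. All 3 neutrophil genes in the table (Camp, Ngp and Mpo, of 25 in the list) and all 3 erythroid genes (Slc4a1 among them, of 20 in the list) were lower. Of all 772 genes of the table, 541 were higher (Fisher's exact test of direction, adjusted p = 0.0398 for each list). The neutrophil granule genes Ngp and Camp had log2 ratios of −1.51 and −1.81. The red cell membrane gene Slc4a1 had a log2 ratio of −1.09. None of these genes passed the adjusted p on its own, and libraries overlapped in Ngp, Camp and Slc4a1 (exact permutation p = 0.0571 for each). Both list calls were lost when only genes with a mean of at least 50 served as background (adjusted p = 0.0912).

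The platelet genes Ppbp and Gp9 had log2 ratios of −1.10 and −1.01 in the Men1 knockout, and −0.36 and −0.33 without WT-6094. The airway secretory genes Retnla, Muc5ac and Agr2 were all higher (Fisher's exact test, adjusted p = 0.558), with log2 ratios of 1.40 for Retnla and 1.13 for the mucin gene Muc5ac. As 541 of the 772 genes were higher, a list with 3 members could pass only as lower, so this p decides nothing. No member of 41 of the 49 lists was in the Men1 table, the alveolar type 1 and type 2 lists among them.

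In Kmt2a knockout lung, many genes changed, in about equal numbers each way. The table holds 3956 genes, all with an adjusted p below 0.05 in the authors' deposited table, 1999 higher and 1957 lower, of which 910 and 1088 changed at least 2-fold. The largest increases included an immunoglobulin variable gene, Ighv1-12 (log2 ratio 6.29), the acyl-CoA thioesterase gene Them5 (5.90), Ankrd63 (6.04), Dthd1 (5.56), Gdf6, a growth factor of the BMP family (5.65), the fibrinogen gene Fgg (5.51), the interferon-inducible Ifi213 (5.40) and the acute-phase gene Orm1 (5.35). Igkv4-90 and the protease inhibitor gene Spink5 also belong here, at means of 61.6 and 83.0 in the knockout and 0.408 and 0.755 in the wild type in the authors' deposited table. These sizes rest on wild-type means of 0.408 to 18.2 in the authors' deposited table: with a pseudocount of 10, the log2 ratios were 2.78 for Igkv4-90, 3.11 for Spink5, 4.70 for Ighv1-12, 4.71 for Ankrd63, 4.97 for Them5, 3.31 for Dthd1, 3.27 for Gdf6, 3.32 for Fgg, 3.845 for Ifi213 and 4.74 for Orm1.

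The largest decreases in the Kmt2a knockout were those of Hist1h2al, annotated as a processed pseudogene (mean 148 in the wild type and listed at 0 in the knockout) and the zinc finger gene Zfp990 (217 and 0.311), as means in the authors' deposited table. Psca, a surface antigen gene of epithelia, fell by a log2 ratio of −6.47, the retinol-binding protein gene Rbp7 by −6.17, the sodium pump subunit gene Atp1a4 by −5.74, neuropeptide Y (Npy) by −5.29 and the interferon-inducible Ifi202b by −4.91. The processed pseudogenes Rps3a3 (−7.20) and Rps3a2 (−6.59) were among them as well, and so was Pcna-ps2 (−6.09), annotated as protein-coding despite its symbol. With a pseudocount of 10, the log2 ratios were −4.46 for Zfp990, −5.15 for Psca, −3.51 for both Rbp7 and Npy, −3.79 for Atp1a4, −2.57 for Ifi202b and −4.87 for Pcna-ps2. In the table, 159 of 183 processed pseudogenes were lower, while 1811 of 3321 protein-coding genes were higher. Whole reads per library could be recovered from the deposited means for 3813 genes, and in 3704 of these (97.1%, against 10% by chance) no knockout library overlapped a wild-type library, in genes selected on these same libraries. The recovered libraries are called a, b and c within each group, since they cannot be tied to labels. Leaving out a single recovered library changed the fold (the ratio of means) by more than 1.5 times in some of these genes: knockout library a for Rbp7 and Igkv4-90, knockout library b for Spink5 and Ighv1-12, and wild-type library a for Ifi202b and Gdf6, b for Ifi213 and c for Dthd1.

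Alveolar epithelial genes rose together in the Kmt2a knockout. In the table, 13 of 14 alveolar type 2 genes were higher (Fisher's exact test of direction against all other genes of the table, adjusted p = 0.00884), with log2 ratios of 4.45 for Chil1, 2.59 for the phosphate transporter gene Slc34a2, 2.47 for lysozyme (Lyz1) and 2.42 for surfactant protein A (Sftpa1). All 10 alveolar type 1 genes were higher (adjusted p = 0.00884), among them Akap5 (2.08), podoplanin (Pdpn, 1.92), Gprc5a (1.40) and Ager (1.37). So were all 7 genes of alveolar repair and injured epithelium (adjusted p = 0.0456), with Krt14 at 3.24, Sfn at 2.34, amphiregulin (Areg) at 1.89 and the integrin gene Itgb6 at 1.85. With backgrounds matched by length, chosen after the data were seen, the repair list stayed close to the threshold. Its adjusted p was 0.0481 against protein-coding genes in its range of lengths and 0.04985 against those nearest in length to each member. Club cell genes went the other way: Cyp2a5 (−2.42), Scgb1a1 (−1.68), Cyp2f2 (−1.55) and Aldh1a1 (−0.81) each fell. The list, with these 4 of its 20 members in the table, did not pass (adjusted p = 0.123). Reads per library were not recovered for Chil1, Slc34a2, Lyz1, Sftpa1, Gprc5a, Ager or the 4 club cell genes. Overlap and left-out libraries could not be judged for them. Without wild-type library a, the log2 ratio of Pdpn was 2.61 and that of Itgb6 2.48. Without wild-type library c, that of Krt14 was 4.40, and with a pseudocount of 10 it was 1.38.

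Muscle genes fell and the matrix genes in the table rose in the same knockout lungs. All 18 cardiac muscle genes in the table were lower (Fisher's exact test, adjusted p = 0.000124), with log2 ratios of −3.91 for Myl3, −3.54 for Tcap, −3.26 for Myl4 and −3.08 for the atrial light chain gene Myl7. The cardiac genes with recovered reads ranked the wild-type libraries in the same order, so a p that takes them as independent can be too small. Of 13 smooth muscle and pericyte genes 11 were lower (adjusted p = 0.0409), with calponin (Cnn1) at −2.39, phospholamban (Pln) at −2.36, Actg2 at −2.20 and Acta2 at −1.48. The wild-type libraries themselves differed widely in these genes: Myl7 lay between 3186 and 13926 normalized counts in the recovered wild-type libraries and between 711 and 1458 in the knockout. All 10 extracellular matrix genes were higher (adjusted p = 0.00884), among them Timp3 (2.02), elastin (Eln, 1.88), Col4a2 (1.53) and Col4a1 (1.49). Longer genes were more often higher in this table, and backgrounds matched by length, chosen after the data were seen, weakened the matrix call. Its adjusted p was 0.0277 against protein-coding genes in the list's range of lengths. Against those nearest in length to each member, of which 64.1% were higher, it was 0.04985. Of 6 adipocyte genes 5 were lower (adjusted p = 0.197). Plin1 and Adipoq had log2 ratios of −3.90 and −3.42, with overlapping libraries, and of −0.81 and −0.84 without wild-type library a (−3.05 and −2.59 with a pseudocount of 10). Leaving out the same library changed the fold of Pln, Tcap and Myl4 by more than 1.5 times, to log2 ratios of −1.30, −2.87 and −2.49. For Acta2, Timp3, Eln, Col4a2 and Col4a1 no reads per library were recovered, so neither overlap nor a left-out library could be judged.

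**Figure D2:**
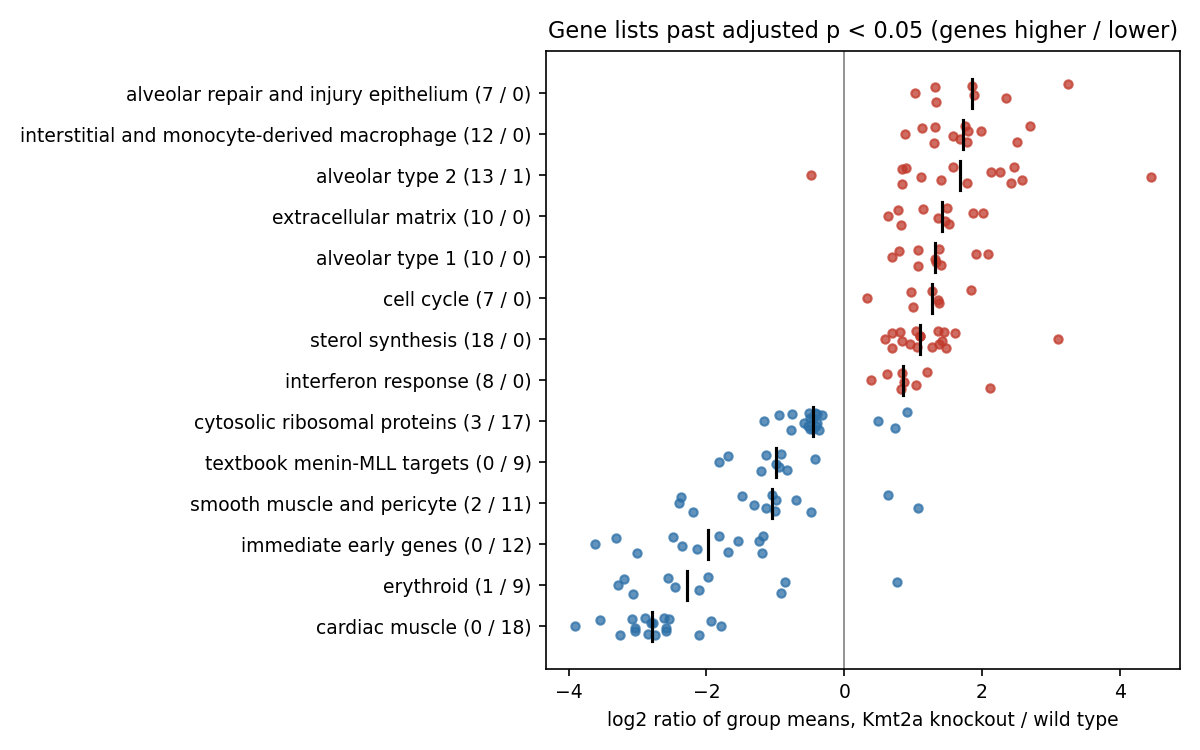
Log2 ratio of deposited group means, Kmt2a knockout over wild type, for each gene (dots) of the lists with an adjusted p below 0.05 in the direction test, with the list median (bars) and the numbers of genes higher and lower.

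Markers of interstitial and monocyte-derived macrophages rose and those of red cells fell in the Kmt2a knockout, while those of alveolar macrophages went both ways. All 12 genes of interstitial and monocyte-derived macrophages were higher (Fisher's exact test, adjusted p = 0.00496), with log2 ratios of 2.70 for osteopontin (Spp1), 2.51 for Ms4a7, 1.98 for C1qb and 1.80 for C1qc. All 6 complement genes in the table were higher too, at an adjusted p of 0.0710, led by the receptor gene C3ar1 (2.55). C1qa, C1qb and C1qc belong to both lists, so the complement genes are in part the same genes. Alveolar macrophage genes divided into 7 higher and 5 lower (adjusted p = 0.831), from Chil3 at 3.19 to Fabp1 at −3.12, the latter with overlapping libraries. All 8 interferon response genes in the table, of 40 in the list, were higher (adjusted p = 0.0319), among them Oas3 (2.11), Iigp1 (1.20), Ifit3b (1.04) and Gbp4 (0.87). Of 10 erythroid genes 9 were lower (adjusted p = 0.0404), among them the globin genes Hba-a2 (−3.28), Hbb-bt (−3.07) and Hba-a1 (−2.55). The 4 platelet genes Gata1 (−2.10, also in the erythroid list), Gp6 (−1.97), Gp5 (−1.37) and Clec1b (−1.29) each fell, with an adjusted p of 0.123 for the list. Without wild-type library a, the log2 ratio of Spp1 was 4.27, that of Oas3 3.05 and that of Fabp1 −1.75. With a pseudocount of 10, that of Fabp1 was −2.03. Without wild-type library b, that of Hba-a2 was −2.56 and that of Gata1 −1.51. Overlap and left-out libraries could not be judged for Hba-a1, Hbb-bt and Chil3, whose reads per library were not recovered.

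Sterol synthesis genes rose in the Kmt2a knockout. All 18 sterol synthesis genes in the table were higher (Fisher's exact test, adjusted p = 0.000153), with log2 ratios of 3.10 for the phosphomevalonate kinase gene Pmvk, 1.61 for Cyp51 and 1.48 for Idi1. Of 16 fatty acid and surfactant lipid genes 13 were higher (adjusted p = 0.0542): the desaturase gene Scd1 stood at 3.63, fatty acid synthase (Fasn) at 2.39 and Fabp5 at 2.22. Fabp4 was lower, at −1.94 with overlapping libraries and at −0.39 without wild-type library a. Of 15 xenobiotic and oxidative stress genes 12 were lower (adjusted p = 0.0542, and 0.0287 against protein-coding genes alone, 0.0472 against genes with a mean of at least 50; with backgrounds chosen after the data were seen, 0.0277 against protein-coding genes in the list's range of lengths and 0.0532 against the 50 nearest in length to each member), including Adh7 (−2.80) and Gsta2 (−1.95), while Cyp2b10 rose (1.54). Without wild-type library c, Adh7 stood at −1.95. Scd1 and Fasn had no recovered reads per library, so their overlap and left-out libraries could not be judged.

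In the Kmt2a table the genes of cell division were higher and most of those of cytosolic ribosomes lower. Most members of both lists were not in the table. All 7 cell cycle genes in the table, of 40 in the list, were higher (Fisher's exact test, adjusted p = 0.0456), among them Bub1b (log2 ratio 1.84), cyclin B1 (Ccnb1, 1.37), Mcm6 (1.37) and Cdc20 (1.28). Of 20 cytosolic ribosomal protein genes in the table (66 in the list) 17 were lower (adjusted p = 0.00884), by amounts such as −1.16 for Rps12, −0.95 for Rpl21 and −0.78 for Rps28. Rplp0 rose (0.91) as its processed pseudogenes fell. For Rpl21 the directions were reversed: the summed mean of its pseudogenes was 1376 in the wild type and 1915 in the knockout. With them added, the log2 ratio of Rpl21 was −0.46. All 5 nuclear genes of the respiratory chain in the table, of 57 in the list, were lower (adjusted p = 0.0710, and 0.0496 against protein-coding genes alone), including Atp5g1 (−0.86) and Ndufa5 (−0.74). All 23 genes of the mitochondrial genome in the table were lower, with log2 ratios from −2.47 to −1.06. Without wild-type library a, the log2 ratio of Bub1b was 2.44. Rplp0 had no recovered reads per library, so its overlap and left-out libraries could not be judged. Short genes were lower more often in this table: 42.3% of protein-coding genes in the fifth with the shortest were higher, against 65.7% in the fifth with the longest. Backgrounds matched by length were therefore added after the data were seen. Against the 50 protein-coding genes nearest in length to each member, the adjusted p was 0.0153 for the ribosomal list, 0.133 for the respiratory chain and 0.04985 for the cell cycle list, and against all protein-coding genes in the cell cycle list's range of lengths that last call was lost (0.0514).

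The homeobox and other textbook target genes of menin and MLL that were in the Kmt2a table fell in the knockout. All 9, of 34 in the list, were lower (Fisher's exact test, adjusted p = 0.00884), with log2 ratios of −1.82 for Hoxa5, −1.69 for Hoxa3, −1.21 for Hoxb7 and −1.14 for Hoxa4. The libraries of Hoxa4 overlapped between the groups. Of the menin and MLL complex list, 3 partner genes were in the table, Aff1 (0.85), Mllt1 (0.63) and Aff4 (0.62), all higher (adjusted p = 0.380).

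Genes that respond quickly to handling, stress or time of day also moved in the Kmt2a comparison. All 12 immediate early genes were lower (Fisher's exact test, adjusted p = 0.00289), with log2 ratios of −3.62 for Egr3, −3.32 for Nr4a1, −3.00 for Nr4a3 and −2.49 for Fosb. Circadian clock genes changed both ways, 5 higher and 8 lower (adjusted p = 0.520). Nr1d1 (−2.75) and Dbp (−2.47) were lower, and Arntl (2.20) and Npas2 (1.94), which peak at the opposite time of day, were higher. Of 9 heat shock and unfolded protein genes 7 were lower (adjusted p = 0.197), including Hspa1b (−2.14), Hspa1a (−2.01) and Dnajb1 (−0.81), while Sdf2l1 was higher (0.86). Leaving out wild-type library b moved Egr3 to −2.88, leaving out knockout library b moved Dbp to −3.57, and leaving out knockout library a moved Npas2, whose libraries overlapped, to 1.28. Nr4a1 had no recovered reads per library and could not be judged in this way.

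Genes present in both tables mostly had the same direction in the Men1 and the Kmt2a knockout, though most of them did not pass the Men1 threshold. Of 70 such genes, 35 were higher in both, 15 lower in both, 18 higher in the Men1 and lower in the Kmt2a knockout, and 2 the reverse. That is 50 of 70 in the same direction (71.4%; Fisher's exact test on directions, p = 0.000149). The test takes genes as independent. Tissue carried along fits liver genes of the Men1 and muscle genes of the Kmt2a libraries (closing section), and was not taken out here. Azgp1, one of those liver genes, was higher in both, though it peaked in KO-6084 and not in KO-6086 like the other liver markers. Lep, of the adipocyte list, was lower in both. A shared effect of the knockouts is therefore not shown by this p. Of the 70, 5 passed the adjusted p in both tables, all in the same direction. Rbp2 had log2 ratios of 2.44 in the Men1 and 2.87 in the Kmt2a knockout, Fst of 1.17 and 2.81, Azgp1 of 1.10 and 1.81, and Hspa1a of −2.70 and −2.01. Hmgb1-ps8, at 2.55 in the Men1 knockout, was listed at 0 in the Kmt2a wild type, with a mean of 11.7 in the knockout in the authors' deposited table, and its libraries overlapped in both.

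The other 8 of the 13 Men1 genes past the threshold have no row in the Kmt2a table used here. Among the 14 shared genes with a mean of at least 50 in both tables, the shared direction was not seen: 7 went the same way (50%; Fisher's exact test, p = 1.00). Without Kmt2a wild-type library c, the Kmt2a log2 ratio of Rbp2 was 4.17, without KO-6075 the Men1 ratio of Hspa1a was −3.37, and without WT-6097 that of Hmgb1-ps8 was 3.48. With a pseudocount of 10, Rbp2 stood at 1.48 in the Men1 and 2.24 in the Kmt2a knockout, and Hmgb1-ps8 at 1.54 in the Men1 knockout. The tables were normalized separately, and by the labels each knockout has its own wild-type mice, so sizes of effects were not tested against each other.

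**Figure D3:**
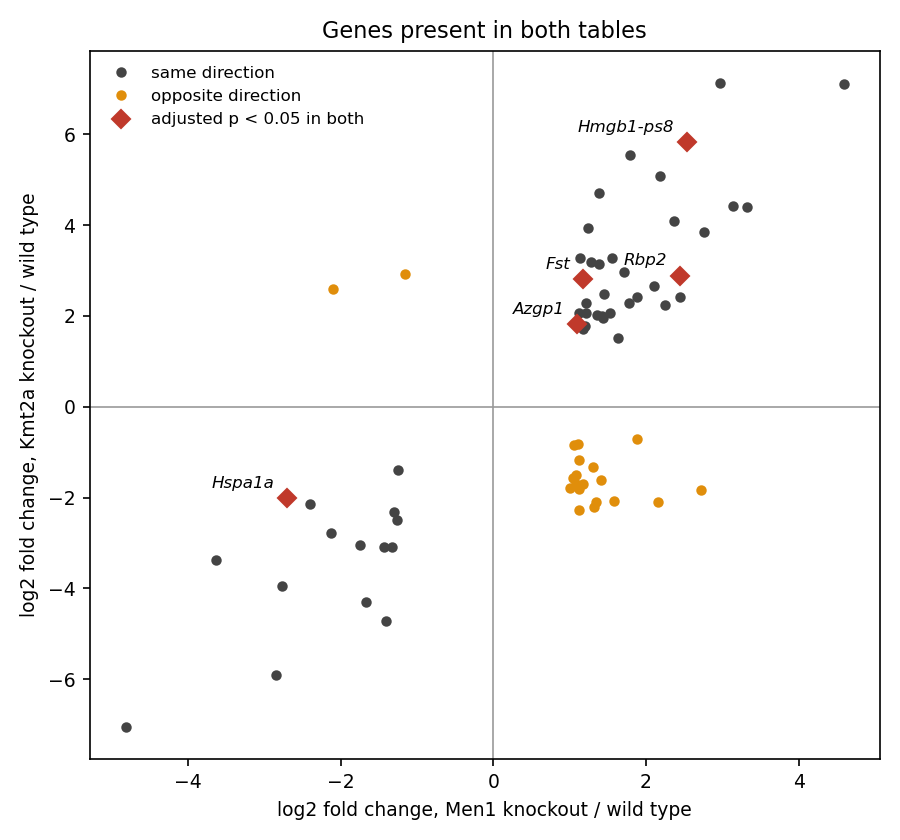
Log2 fold changes in the authors' deposited tables of the 70 genes present in both, Men1 knockout against Kmt2a knockout. Genes with an adjusted p below 0.05 in both tables are named.

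Counts at some ribosomal protein genes and at their processed pseudogenes differed in opposite directions between the Kmt2a groups. In the wild type, Rplp0 and its processed pseudogenes stood at means of 10476 and 10878 in the authors' deposited table. In the knockout the parent stood at 19716 and the pseudogenes at 46.5. Rps3a1 and its 4 pseudogenes stood at 7488 and 13942 in the wild type and at 18141 and 140 in the knockout. For Rpl3 the parent stood at 8228 and its pseudogenes at 5352 in the wild type, against 13734 and 1251 in the knockout, as means in the authors' deposited table. The sums over parent and pseudogenes had log2 ratios of −0.11, −0.23 and 0.14. These families were picked after their values were seen, and others differ: among all 8 whose pseudogenes had at least 10% of the wild-type level and a log2 ratio of −2 or lower, the sums also stood at −2.97 for Eno1b, 1.85 for Fabp5, 0.79 for Dnajc17, 0.67 for Rbpj and 0.22 for Rpl15. For Rps12, Rps24, Rps27a, Rpl13 and Rpl9, whose pseudogenes had a smaller share, parent and pseudogenes were both lower (sums from −1.17 for Rps12 to −0.34 for Rpl13).

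**Figure D4:**
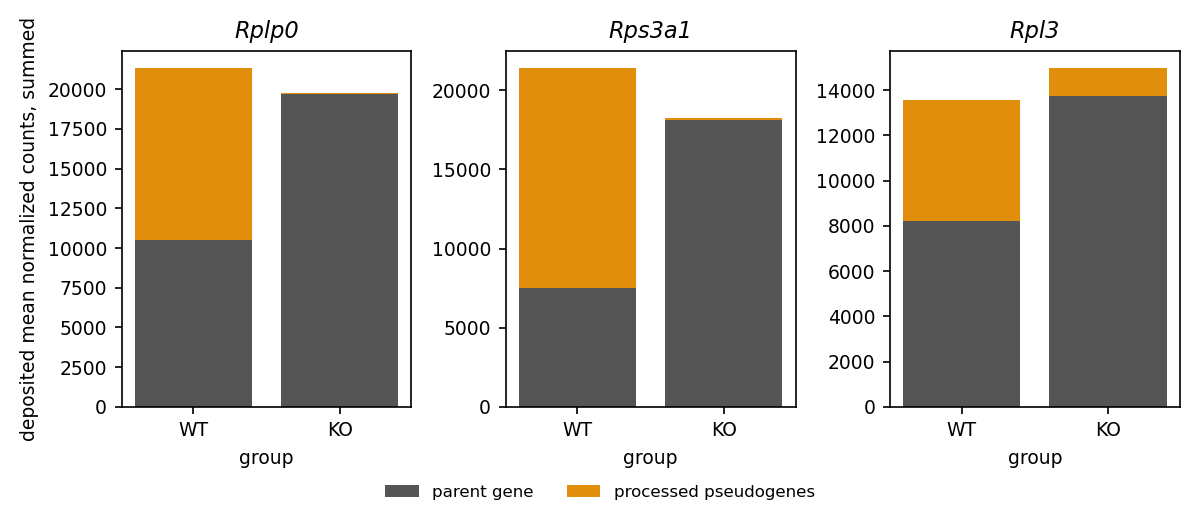
Mean normalized counts in the authors' deposited table, Kmt2a wild type (WT) and knockout (KO), of 3 ribosomal protein genes and, stacked above, of their processed pseudogenes.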

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

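All tests in this part, and the bounds they use, were chosen after the results were seen. In the Men1 groups of 4, a library far from the others was found in 4 of 42 groups of values tested for the named genes, where chance gives about 2.1 (1 in 20). For Dmbt1, KO-6086 (240 normalized counts, against 4.72 to 11.3) was set apart by a gap of 0.972 of the range. For Hebp2, KO-6075 (103, against 113 to 115) was set apart by 0.875, with little difference in level. The platelet genes Ppbp (2797 in WT-6094, against 583 to 899; 0.857 of the range) and Gp9 (733, against 196 to 237; 0.924 of the range) stood apart in the same wild-type library. Of the genes of both tables without overlap between libraries in either, 16 had the same direction in both knockouts. In 7 the knockouts differed from their wild types in opposite directions: Selenbp2, Gm7334, Cyp2b19, Gm13408, Nags, Gm8566 and Rpl17-ps5 were all higher in the Men1 and lower in the Kmt2a knockout. None of the 7 passed the Men1 threshold (adjusted p of 0.110 for Selenbp2, 0.113 for Cyp2b19, 0.124 for Gm8566, 0.146 for Nags and 0.171 for Gm13408 in the authors' deposited table, which gives none for Gm7334 and Rpl17-ps5). Selenbp2 had log2 ratios of 2.16 and −2.09 and Cyp2b19 of 1.42 and −1.61, and the difference between the knockouts was not tested.

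Processed pseudogenes were lower in the Kmt2a knockout, and 8 families had pseudogenes with at least 10% of the wild-type level and a log2 ratio of −2 or lower. The same reads being counted at another copy of the gene, as a mapping difference could give, stays open: the parent gained between 50% and 200% of its pseudogenes' loss in 3 of the 8 (85.3% for Rplp0, 77.2% for Rps3a1 and 134% for Rpl3), more than 200% in 4 (Fabp5, Dnajc17, Rbpj and Rpl15), and Eno1b was lower with its pseudogenes (log2 ratios −3.03 and −2.71). Less transcription of the pseudogenes alone would lower the sum over parent and pseudogenes. The sum lay within a log2 ratio of 0.25 of the wild type in 4 of the 8. It lay above that for Fabp5 (1.85), Dnajc17 (0.79) and Rbpj (0.67), and below only for Eno1b (−2.97). The parent was higher in 7 of the 8. That argues against less transcription as the only change in these families, whose parents had all passed the filter of the table. As 1 change among others, or for other pseudogenes, it stays open. Loss of short transcripts as the whole cause is argued against only weakly. Of 183 processed pseudogenes 86.9% were lower, against 61.7% of 230 protein-coding genes of 309 to 1339 bases. That range covers most of the pseudogenes, but lengths were not matched within it, and shorter genes were lower more often. For 127 of the 183 no parent is in the table.

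Cardiac muscle genes were lower in the Kmt2a knockout and uneven within the wild type. Wild-type library a exceeded b by a median of 5.39 times in these genes. In all other genes with a level above 50 it did so by 1.01 times. A value near 1 there follows largely from the size factors the counts were divided by, and does not test them. The gap between the 2 sets of genes argues against library size or a wrong size factor, which would move all genes alike. Other faults of normalization were not tested. All 16 cardiac genes with recovered reads ranked the wild-type libraries in the same order (a, c, b), an order found in 14.5% of other genes, and so did all 5 resolved adipocyte genes. That fits muscle tissue carried along in different amounts, as heart or pulmonary vein muscle could be. A fall within muscle cells of the knockout stays open: the wild-type libraries lay 5.39 times apart at the median, the lowest of them lay 1.61 times above the highest knockout library at the median, and the libraries of the groups overlapped in 4 of the 16 genes.

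Some liver genes had higher means in the Men1 knockout, of which only Apob and Azgp1 passed the threshold; whether liver genes as a set were higher was not tested. Of 41 textbook liver markers, listed after such genes had been seen in the Men1 table, 16 were in it, all higher like 541 of its 772 genes, and 15 of the 16 peaked in KO-6086. A knockout effect in every animal stays open: the libraries of the groups overlapped in 14 of the 16, as they did in 498 of all 772 genes, and without KO-6086 the median log2 ratio of the markers was 0.81, against 1.76 with it. KO-6086 exceeded the mean of the other knockout libraries by a median of 5.11 times in the markers and 1.03 times in 231 other higher genes. A value near 1 there follows largely from the size factors the counts were divided by. The gap between the 2 sets of genes argues against library size or a wrong size factor, which would move all genes alike. Other faults of normalization were not tested for KO-6086. Liver tissue carried along in single libraries fits, while Apob and Azgp1, which did not overlap between the groups, are not set apart by that library alone. Of the 16 markers, 13 were lowest in KO-6084 among the knockout libraries, while Azgp1 was highest there (484 normalized counts, against 480 in KO-6086).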

How the results depend on the processing

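The edgeR tests, the left-out recovered libraries (Kmt2a a, b and c) and the list backgrounds matched by gene length were chosen after the data were seen. The genes had been selected on the same libraries, and no call could be made anew without 1 of them. Directions, list counts (14 and 2), the 13 Men1 and 3813 resolved Kmt2a genes and the 71.4% of shared directions were therefore all but fixed beforehand when 1 library was left out, and their not changing says nothing of robustness. The count of Men1 genes past the threshold was 13, and 13 with an absolute log2 fold change of at least 1 or a mean of at least 10. It was 1 at an adjusted p below 0.01, 274 by non-overlap, and 4 with edgeR on the selected genes at the authors' largest p among calls, 2 of them shared; that test gave 1 to 11 calls with 1 library left out. The Kmt2a count of 3956 became 2432 at an adjusted p below 0.01, 1998 with an absolute log2 fold change of at least 1, 3900 with a mean of at least 10, 3704 by non-overlap and 2623 of 3813 with edgeR on the recovered reads (1442 to 2204 with 1 library left out). Medians in place of means left the direction of all 13 and all 3813. Shared direction in both tables was 71.4%, 74.6% with an absolute log2 fold change of at least 1 in both, 65.5% with means of at least 10, 77.1% in protein-coding genes and 50% with means of at least 50 (14 genes, Fisher's exact p = 1.00; fewer genes are tested there). No gene had an adjusted p below 0.01 in both tables. Gene lists past the threshold numbered 14 in the Kmt2a comparison (15 against genes with a mean of at least 50, 16 against protein-coding genes, 14 with either background matched by length, of which that of the list's range of lengths lost the cell cycle list) and 2 in the Men1 comparison (0 against genes with a mean of at least 50, where fewer genes are tested). Leaving out 1 library changed the fold (the ratio of means) by more than 1.5 times in 5 of 16 named Men1 values and 28 of 92 Kmt2a values. A pseudocount of 10 changed it by that much in 4 of 16 Men1 and 23 of 114 Kmt2a values, and a pseudocount of 1 in 1 and 4, with no change of sign. Other normalizations and DESeq2 were not run on these selected genes.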

Other observations

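Some gene classes outside the lists also leaned one way in the Kmt2a knockout. All 5 T cell receptor constant genes, all 12 microRNA genes and 10 of 11 small nucleolar RNA genes in the table were lower. Immunoglobulin variable genes divided into 11 higher and 7 lower. Longer protein-coding genes were more often higher: 42.3% in the fifth with the shortest genes, up to 2215 bases, then 51.9%, 54.9%, 58.0% and 65.7% in the fifth with the longest. These values were looked at after the table was seen, and no test was made.

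Some genes were almost all or nothing between the Kmt2a groups. A group mean of 0 occurred in 64 of 3956 genes of the Kmt2a table and in 41 of 772 genes of the Men1 table. It can stand against a low level in the other group. In the authors' deposited Kmt2a table, Lep had 9.74 in the wild type and Hmgb1-ps8 had 11.7 in the knockout. The count alone therefore does not show genes switched on or off, least of all in the Men1 table with its median mean level of 5.63. Ifi213 (log2 ratio 5.40) and Ifi202b (−4.91), members of a family of interferon-inducible genes on chromosome 1, changed in opposite directions, with no overlap between libraries. In the Men1 table, Gm6314 had 1 to 3 raw reads in each knockout library and 73 to 223 in each wild-type library.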
